A study of Sorghum bicolor with 4 samples.

How the data were processed

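Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used on sorghum mesophyll protoplasts, leaf cells stripped of their walls, that transiently expressed SbGhd7. The 4 samples form 2 groups with 2 samples each, input chromatin and chromatin pulled down with an anti-Myc antibody (IP). Per the labels' protocols, cells were kept at 24 °C overnight, fixed for 8 minutes in 1% formaldehyde and sonicated. Libraries were made from 50 to 100 pg of DNA, amplified over 18 cycles and size-selected at 200 to 500 bp. No label describes an IP from cells without SbGhd7. The labels do not say whether the samples with the same number came from separate protoplast preparations.

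The authors deposited 1 list of narrow peaks in 10 columns, with no header and no values per sample. BWA 0.7.17.2 and MACS2 2.2.7.1 are named in the submitters' processing notes; their settings, the genome build and the treatment of replicates are not given in the sources used here. All peak names carry 1 alignment name that includes a mark for duplicate marking, so whether the list rests on 1 library or on pooled libraries is open. Column 7 of the deposited list is a fold ratio of IP over local background at the summit. Columns 8 and 9 of the deposited list are the −log10 of the p-value and of the q-value. Column 5 of the deposited list is a score equal to 10 times column 8 truncated to a whole number, except in 2 rows. The smallest −log10 p was 3.00 and the smallest −log10 q was 1.25, so every peak had a p under 0.001 while 215 peaks had a q over 0.05. Start, end and summit are given 1-based below, in the coordinates of the deposited list.

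The pileup behind each peak was recovered from the list. MACS2 is known to compute the fold as pileup plus 1 over background plus 1, and the p-value as the Poisson probability of more than the pileup given the background. The added 1 lowers the fold more where the background is low, so folds at different backgrounds are not on the same footing. These 2 values fix both unknowns, and all 40087 peaks gave 1 and only 1 whole-number pileup whose −log10 p matched the list within a relative tolerance of 2e-05. On 4649 simulated peaks written with the same number of digits, 100% of the pileups were recovered, and the largest error of the background was 0.0005%. The pileup counts IP fragments over the summit, and the background is the number expected there from the control, taken here to be the input libraries, which the list itself does not state. Total reads per sample are not part of the list, so the depth of each library is unknown. Intervals on a pileup are exact Poisson intervals at 95%, as are those on the peak density of a chromosome, taken from its count of peaks. Intervals on a fold hold the background fixed, and intervals on a share are exact Clopper-Pearson intervals. All cover counting error only, and fragments amplified without molecular identifiers are not independent molecules. None is adjusted for reading the pileup at the summit or for picking peaks by their fold, so lower limits of picked peaks can be too high. The peaks are not replicates, and no spread between samples could be computed.

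The length of each chromosome was taken as the end of its last peak, which is a lower bound. The end regions are the first and last 25% of that length, and the middle region is the 50% between them. Peak densities in the end regions and the middle region were compared over the 10 chromosomes with an exact two-sided sign-flip test. Peaks with a fold of 8 or more were compared with the other chromosome peaks by an exact two-sided conditional test stratified by chromosome. That test treats peaks as independent, so the folds were also rotated along the peak order of each chromosome, 100000 times, which keeps neighbouring folds together. The rotation p was corrected for the 13 classes and thresholds of fold that had been viewed, by the largest scaled deviation, and multiplied by 3 for the classings viewed. In a further test, peaks with a fold of 8 or more were compared with other peaks of the same chromosome and of the same of 8 classes of background. Among 100 lists of rotated folds, 4 had a p under 0.05 after correction over the classes and thresholds. These lists were made by the same rotation, so they check the computation and not whether rotation suits these data. Among 100 simulated lists with no effect, the sign-flip test gave p under 0.05 in 2 lists and the stratified test in 3. Peaks in those lists were placed evenly and independently, so clustering of peaks was not covered. In a list simulated with a density ratio of 0.538 the ratio recovered was 0.562. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

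Tests of promoters, gene features, gene lists and motifs had been fixed before the data were examined. They were not run, because no genome sequence was used here, and because the coordinates of the RefSeq gene table at hand were not used, since the sources used here name no build for the peaks. The rule for named genes could not be applied either, so no gene is assigned to a peak. In its place the regions with the 10 largest folds, the 10 largest −log10 q values, the highest backgrounds and the densest 1 Mb windows are named. These rankings and all of the tests, regions and thresholds reported here were chosen after the list had been examined. The threshold of a fold of 8 was picked after the share of peaks in the end regions had been viewed by 3 classings, of fold, pileup and background, so the p-value that rests on it is not that of a test fixed beforehand. Alternatives tried were stricter q and fold thresholds, other fold and background thresholds, other sizes of the end regions, peaks of low background and 1 peak per 10 kb cluster. A 10 kb cluster is a run of peaks in which each summit lies within 10 kb of the one before. Such a run can span more than 10 kb, and only its peak of highest fold was kept.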

Results

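The study asked where SbGhd7, a transcription factor with a CCT domain that represses flowering in sorghum, binds in the genome of mesophyll protoplasts. Myc IP and input chromatin were each sequenced in 2 samples, and the comparison between them reached GEO as a single list of 40087 peaks. Of these, 35541 lay on the 10 chromosomes and 4546, or 11.3%, on 354 unplaced scaffolds. The peaks covered 11.8 Mb, and those on chromosomes covered 1.45% of the chromosome lengths. No value in the list belongs to 1 sample, so a difference between replicates cannot be set beside any result, and each fold, p and q is the authors' own value for the peak.

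Most peaks were weak. The median fold enrichment was 3.70, with 3.26 and 4.27 as quartiles. A fold of 5 or more was reached by 3297 peaks, or 8.22%, and a fold of 10 or more by 29. A q of 0.05 or less was reached by 39872 peaks, a q of 0.01 or less by 35019 and a −log10 q of 5 or more by 8372. The median peak was 225 bp wide and rested on 12 IP fragments at its summit over a background of 2.39 fragments, and 90.0% of peaks had a pileup of 20 or less. A count of 12 has a 95% interval of 6.20 to 21.0. A peak with this pileup and background has a fold of 3.84 with an interval of 2.13 to 6.48. Both quartiles of the fold lie inside this interval.

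**Figure D1:**
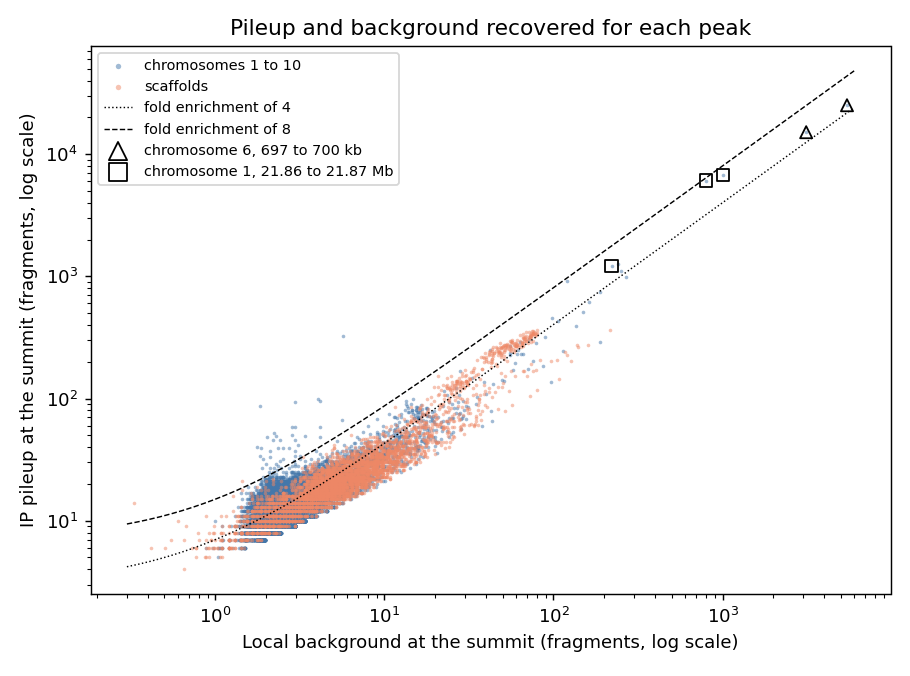
IP pileup at the summit (fragments, log scale) against local background at the summit (fragments, log scale) for each of the 40087 peaks, with chromosome peaks in blue and scaffold peaks in orange; the curves mark a fold of 4 and of 8, and open symbols mark 5 peaks on chromosomes 6 and 1. Most peaks sit near a pileup of 12, a few chromosome peaks lie above the curve for a fold of 8 at backgrounds up to 5.70, and the marked peaks have backgrounds from 220.4 to 5443.

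The largest fold was found on chromosome 3 at 7496019 to 7496218. It was 49.0 (95% counting interval 43.8 to 54.6), from a pileup of 327 over a background of 5.70, which is above the 95th percentile of chromosome peaks, 4.38. On chromosome 2, the peak at 22194064 to 22194316 had a fold of 30.9 (24.8 to 38.0), the peak at 5008290 to 5008704 a fold of 23.8 (19.2 to 29.0), and the peak at 67693204 to 67693435 a fold of 19.8 (16.1 to 24.1). On chromosome 5, the peak at 4819842 to 4820159 had a fold of 18.6 (15.1 to 22.7) and the peak at 7078779 to 7079010 a fold of 16.4 (12.3 to 21.4). The peak on chromosome 10 at 11104167 to 11104426 had a fold of 16.3 (12.1 to 21.5). The next 3 folds were 15.3 on chromosome 2 at 66665937 to 66666107, 15.2 on chromosome 4 at 4070334 to 4070508 and 14.9 on chromosome 1 at 51454129 to 51454583. The interval of the chromosome 3 peak lay above those of the other 9 peaks, while the intervals of neighbours in this ranking overlapped. Altogether 46 chromosome peaks had a fold of 8 or more, and at least 1 lay on each chromosome, with 8 on chromosome 1, 8 on chromosome 2 and 1 on chromosome 8. For 23 of the 46 the lower end of the counting interval was above 8. Their median pileup was 39 and their median background 2.38, against 12 and 2.30 for the other chromosome peaks.

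Ranked by −log10 q, the list was led by other regions. The top values were 8132 for the peak on chromosome 6 at 697474 to 697899 and 5140 for the peak on chromosome 6 at 699820 to 700090. The next 3 lay together on chromosome 1, with 3095 at 21865404 to 21865993, 3064 at 21866382 to 21866693 and 471.7 at 21862151 to 21862740. Their folds were 4.61, 4.84, 6.74, 7.61 and 5.53 in that order, all below the threshold of 8. Their backgrounds ranged from 220.4 fragments, for the last of them, to 5443 for the first, where the median over all peaks was 2.39. The next 2 values lay within the first 5 kb of chromosome 4, with 469.3 at 3363 to 3661 and 457.8 at 2576 to 2874. The chromosome 3 peak at 7496019 followed with 433.4, then the last peak of chromosome 5 at 71854467 to 71854650 with 333.0, and the peak on chromosome 9 at 80 to 436 with 240.6. A background of 50 or more fragments was found at 157 peaks, 36 of them on chromosomes. Of these 36, 9 lay within 5 kb of the first base or of the last peak end of chromosomes 4, 5, 7, 9 and 10.

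Peaks were sparser toward the chromosome ends. The end regions, defined as the first and last 25% of each chromosome, held 12364 of 35541 chromosome peaks, or 34.8% (95% interval 34.3 to 35.3), where an even spread gives 50%. The density was 36.4 ± 6.17 peaks per Mb (SD, n = 10 chromosomes) in the end regions and 67.6 ± 6.30 in the middle region. It was lower outside than inside on 10 of 10 chromosomes (exact sign-flip p = 0.00195, the smallest this design can give). The ratio of the outer to the inner density ranged from 0.437 to 0.663 between chromosomes. Over whole chromosomes, the density was lowest on chromosome 4, at 41.6 peaks per Mb (40.1 to 43.1), and highest on chromosome 8, at 58.8 (56.9 to 60.7). Both intervals treat peaks as independent, so they are too narrow where peaks cluster. The densest 1 Mb windows were 47 to 48 Mb of chromosome 5, with 245 peaks, and 22 to 23 Mb of chromosome 6, with 206 peaks, against a median of 50 per occupied window. In the 10 densest windows the median background ranged from 2.24 fragments, at 31 to 32 Mb of chromosome 1, to 5.45, at 46 to 47 Mb of chromosome 5. It was 2.30 over all chromosome peaks. On 7 chromosomes a stretch of over 1 Mb held no peak, the longest being 4.85 Mb on chromosome 1 from 40803333 to 45655153 and 4.32 Mb on chromosome 4 from 28430079 to 32752980. Elsewhere on the chromosomes the longest stretch without a peak was 0.565 Mb.

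**Figure D2:**
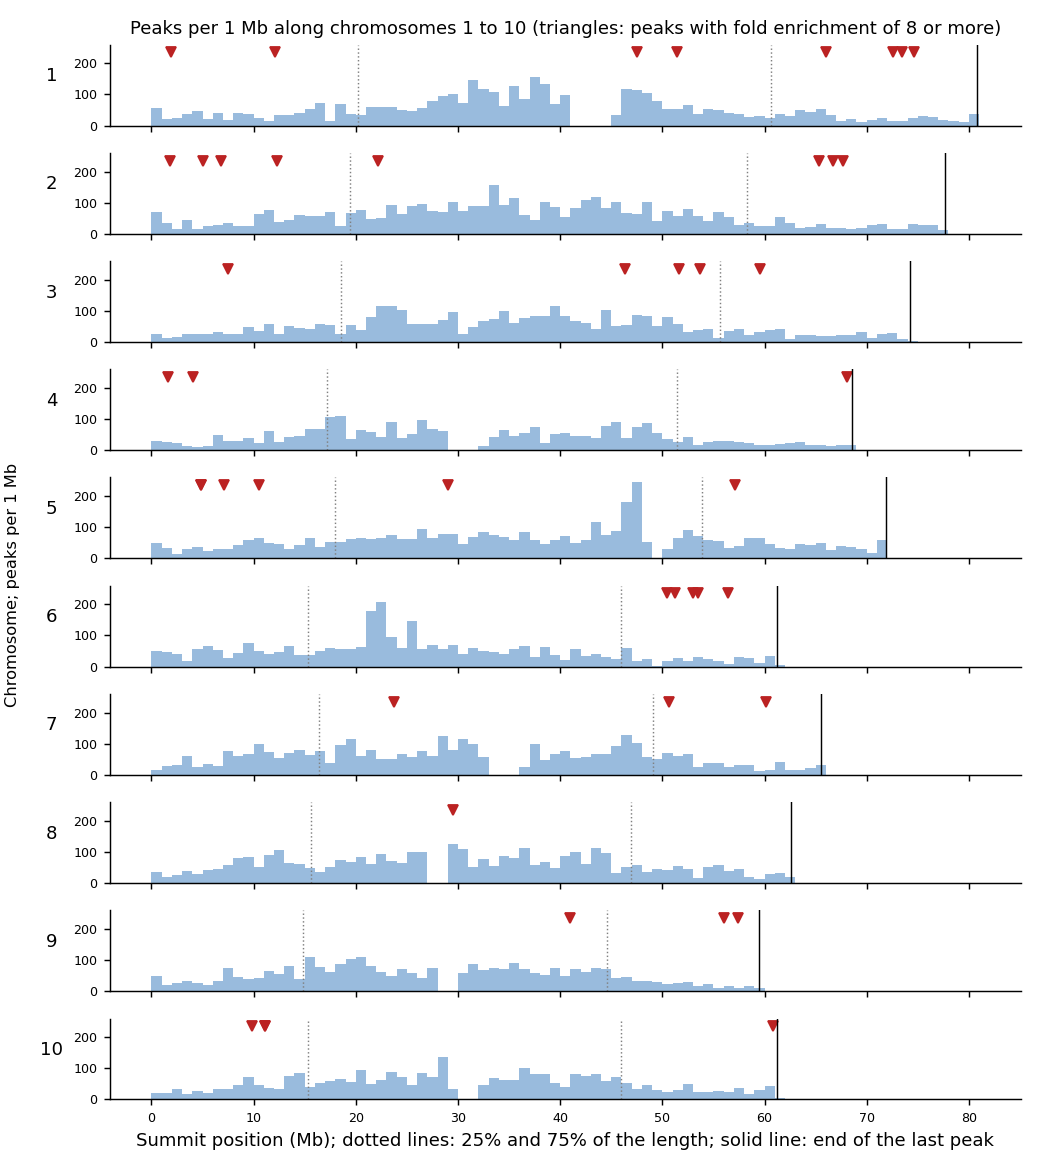
Number of peaks per 1 Mb (vertical axis) by summit position in Mb (horizontal axis) on chromosomes 1 to 10, with red triangles at the 46 peaks with a fold of 8 or more, dotted lines at 25% and 75% of the length and a solid line at the end of the last peak. Peaks are densest in the middle region, while 36 of the 46 triangles lie in the end regions.

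The peaks with the highest folds were placed differently. Of the 46 peaks with a fold of 8 or more, 36 lay in the end regions, or 78.3% (63.6 to 89.1), against 34.7% (34.2 to 35.2) of the other 35495 chromosome peaks. The difference of 43.5 percentage points had an exact two-sided p of 7.59e-10 in the test stratified by chromosome. That p treats peaks as independent, and the threshold of 8 was chosen after these shares had been seen. With folds rotated along the chromosomes and a correction for the choice, the permutation p was 0.0024. The share did not rise steadily with the fold. It was 33.7% (32.2 to 35.2) below a fold of 3, 32.5% (30.7 to 34.4) at folds of 5 to 6 and 35.0% (30.2 to 39.9) at folds of 6 to 7. It was 43.5% (31.0 to 56.7) at folds of 7 to 8, 77.8% (52.4 to 93.6) at folds of 8 to 10 and 78.6% (59.05 to 91.7) at 10 or more. By pileup the share took another course among peaks with a background under 5. It was 37.4% (36.5 to 38.3) at pileups of 10 or 11 and fell to 23.3% (20.3 to 26.5) at 20 to 24. It was 39.6% (25.8 to 54.7) for the 48 peaks with a pileup of 30 to 49 and 66.7% (29.9 to 92.5) for the 9 peaks above that. Median peak width rose from 183 bp below a fold of 3 to 400 bp at folds of 6 to 7, and was 228 bp at folds of 10 or more. With a threshold of 6 in place of 8, which takes in 497 peaks, the difference was 5.33 percentage points (exact p = 0.0117), and the corrected rotation p was 0.46.

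**Figure D3:**
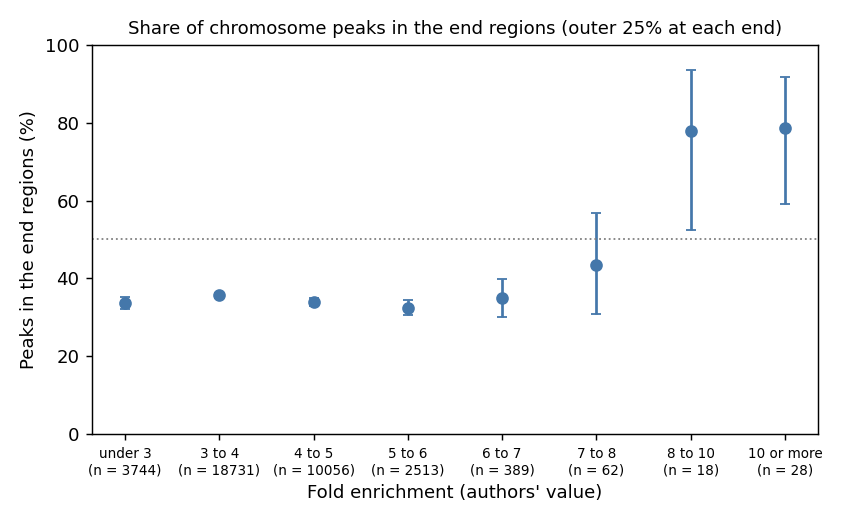
Percent of chromosome peaks in the end regions (vertical axis) by class of fold enrichment (horizontal axis, number of peaks under each class); bars are exact 95% binomial intervals and the dotted line is the 50% of an even spread. Classes below a fold of 7 lie between 32.5% and 35.6%, and both classes from a fold of 8 up lie above 77%.

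Scaffold peaks had a higher background than chromosome peaks, with a median of 5.23 against 2.30 fragments, and 53.3% of them had a background of 5 or more, against 3.77% on chromosomes. Their median fold was 3.44 (quartiles 2.95 and 4.11), against 3.74 (3.31 and 4.28) on chromosomes, where the lower background makes the added 1 weigh more. Relative to the length up to the last peak, scaffolds held 215.3 peaks per Mb and chromosomes 52.0, although this length falls short of the true one by more on short scaffolds. Scaffolds without a peak add no length here, which raises the scaffold density. The value holds only for the 354 scaffolds with a peak. The ratio of these densities was 4.14. It was 2.01 among peaks with a background under 5, 2.54 with 1 peak per 10 kb cluster and 9.19 among peaks with a −log10 q of 5 or more. The scaffold super_57 was covered over 94.2% of the 134.0 kb up to its last peak, an upper bound on its covered share. It held 12 peaks, the longest of 33.5 kb, with folds from 4.12 to 5.44 and a median background of 74.3. The first 200 kb of super_16 was covered over 88.3%, with a median background of 51.0, and the rest of that scaffold over 7.54%, with a median background of 4.37. Over the 56 scaffolds that reach 100 kb, the median covered share was 6.05%. Some shorter scaffolds were also covered almost wholly at a high background. Up to its last peak, super_1157 was covered over 96.9% and super_527 over 89.3%, with median backgrounds of 67.5 and 73.6.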

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

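All of the alternatives and tests here were chosen after seeing the data. Those fixed earlier concerned promoters, gene features, gene lists, motifs and k-mers. They were not run, because no genome sequence was used and no build is named for the peaks in the sources used here. No paired analysis was possible because the list has no values per sample, and for the same reason no replicate could be left out. The ratio of peak density in the end regions to that in the middle region stayed below 1 with the same p under all 7 alternatives, from 0.445 with a −log10 q of 5 or more to 0.731 with 1 peak kept per 10 kb cluster. The excess of peaks with a fold of 8 or more in the end regions kept its direction and, by the exact test, stayed past 0.05 under all 8 alternatives, from 5.33 percentage points with a fold of 6 to 48.3 with end regions of 20% each. By the rotation test, which keeps neighbouring folds together, the p corrected for the choice was 0.0024 at 8, 0.00852 at 7 and 0.0343 at 10. It was 0.46 at 6, where the 5.33 points no longer passed. The rotation p at 6 was 0.021 before the correction, so the correction for the choice removed the call. The number of peaks was 40087 as deposited, 8372 with a −log10 q of 5 or more and 20120 with a fold at or above the median. The number of chromosome peaks past the fold threshold was 46 at 8, 497 at 6, 108 at 7 and 28 at 10, and 23 where the lower counting limit had to reach 8. The number of peaks with high background was 157 at 50 fragments, 466 at 20 and 25 at 100. With only the scaffolds that hold a peak counted in the length, the ratio of scaffold to chromosome peak density was 4.14. It was 9.19 with a −log10 q of 5 or more, 2.01 with a background under 5 and 2.54 with 1 peak per 10 kb cluster. The counts moved because each threshold keeps another number of peaks; for the density ratios the cause was not tested. Of all peaks, 90.0% rest on 20 or fewer fragments at the summit, which limits the precision of their folds.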

Other observations

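All of the tests in this part were chosen after the results they concern had been seen, and each explanation is a hypothesis.

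The 5 peaks with the largest −log10 q, at 697474 to 700090 on chromosome 6 and 21862151 to 21866693 on chromosome 1, had backgrounds of 220.4 to 5443 fragments, where the 99th percentile of chromosome peaks was 9.97. If the background comes from the input, this argues against sites present once per genome copy. The ranking itself favours high backgrounds, since at a given fold the −log10 q rises with the background. The chromosome 3 peak, with 433.4 and a background of 5.70, had a fold of 49.0. All others among the 10 largest −log10 q values had a background of at least 121.0. The high background did not reach the nearest peaks on either side, which had backgrounds of 1.95 to 2.30. These lay 9.60 kb and 64.5 kb away on chromosome 6 and 92.7 kb and 15.3 kb away on chromosome 1. Background is known only at summits, so the list does not show where between these peaks it falls. A candidate explanation is DNA of a transfected plasmid that carries these sequences; elsewhere 0 chromosome peaks had a background of 500 or more, but 3 peaks near the ends of chromosomes 9, 5 and 4, with 269.4, 249.5 and 240.0 fragments, exceeded the lowest of the 5. A repeat collapsed into 1 copy of the assembly would look alike, and neither genes at these positions nor plasmid sequences were used here, so the plasmid and the repeat both stay open. Both concern the background, and neither by itself says why the folds of the 5 peaks were 4.61 to 7.61. Chromosome peaks with a background of 50 or more, these 5 among them, had a median fold of 3.88.

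The peaks with a fold of 8 or more may be of another kind than the rest of the list. Their excess in the end regions had a permutation p of 0.0024 with folds rotated along the chromosomes. That p was corrected for the fold threshold, though not for the size of the end regions, and argues against a chance ranking. Against other peaks of the same chromosome and background class the excess was 46.3 percentage points (exact p = 3.83e-11 with peaks taken as independent). At the same background a lower fold means a lower pileup, so this test did not compare peaks of equal pileup. It cannot decide whether higher background in the chromosome centres kept peaks there below a fold of 8. By background, the share of chromosome peaks in the end regions was 38.2% at 2 to 2.5 and 14.3% at 4 to 5. It was 6.29% at 5 to 10 and 32.9% at 10 or more, and that cause stays open. Over all of them the median width was 240.5 bp, against 223 bp for the other chromosome peaks, whose pileups are lower; at pileups of 25 to 59 and a background under 6 it was 228 bp for 38 of them and 391 bp for 225 weaker peaks, a ratio of 0.583 (two-sided permutation test of 100000 resamples, p = 2e-05, the smallest it can give), and 217 bp for 31 against 405 bp for 25 within the end regions (p = 0.00062). In both width comparisons pileup and background were held only to these ranges. For a given pileup a lower fold means a higher background, so the weaker peaks were not matched on background. These width tests therefore cannot decide whether the narrower width goes with the kind of peak or with the lower background. Stacked fragments such as amplification duplicates would be narrow, but so would a short, sharply bound site. The alignment name also carries a mark for duplicate marking. Binding sites in gene-rich chromosome ends, where 78.3% of these peaks lie, therefore stay open as well, since no gene annotation was used.

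The scaffold super_57 stood out by its coverage of 94.2%, up to its last peak, among the 56 scaffolds that reach 100 kb. The next highest was 45.9%. Some shorter scaffolds had a like coverage and median background, such as super_1157 (96.9%, 67.5), super_2493 (96.5%, 70.9) and super_527 (89.3%, 73.6), so the trait is not particular to super_57. The peaks of super_57 had a median width of 8718 bp, against a 99th percentile of 957 bp on chromosomes. This width follows from that coverage and decides nothing about binding sites. Every background on it was at least 20.2 times the chromosome median. If the background comes from the input, DNA in many copies per cell, such as an organelle genome, could give this. Copy number by itself does not say why the folds on super_57 were 4.12 to 5.44, since a fold is taken over the background. Scaffold peaks with a background of 50 or more, some of them on super_57, had a median fold of 4.39. Their 5th and 95th percentiles were 1.69 and 5.16. The cause of these folds was not tested. The sequence of super_57 was not examined, so a nuclear repeat array is not excluded, and binding of the protein to such copies stays open.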
